A study of Xenopus laevis with 12 samples.

How the data were processed

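The series holds 12 whole-brain RNA-seq libraries of Xenopus laevis tadpoles in 4 groups of 3. The groups are untreated controls and thioridazine-exposed animals, each at Nieuwkoop-Faber (NF) stages 45 and 47. Per the labels' protocols, embryos were exposed to 90 µM thioridazine, a phenothiazine antipsychotic that blocks dopamine receptors, from NF 14 to NF 26 at 18 °C. Plates held 50 embryos in 10 mL, and the embryos were otherwise reared at 14 °C until they fed. Per the labels' protocols, total RNA was DNase-treated, made into Illumina TruSeq libraries and sequenced as single-end 100 bp reads.

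The authors deposited 1 table of raw read counts per library, with a whole-number count for each of 37018 NCBI Gene numbers. The submitters' processing notes name Trimmomatic, HISAT2, HTSeq and DESeq2. Versions, genome build, annotation release, strand setting and the treatment of reads that match several places were not given in the sources used here. The deposited counts carry no normalization and no summary lines for unassigned reads. Xenopus laevis is allotetraploid, so many genes have a .L and a .S copy of similar sequence, and reads could be split between such copies during counting. Values of single copies, of members of multigene families and of overlapping or antisense genes are therefore uncertain by an unknown amount.

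Gene numbers were matched to symbols in an NCBI RefSeq gene table of a later Xenopus laevis assembly, which was used for names and for no coordinates. It named 33597 of the 37018 numbers, which held 99.33% of all reads. The other 3421 numbers stayed in the tests without a name. Genome positions were not used here. Total counts per library ran from 12843954 to 18164871, and between 30408 and 30979 genes had at least 1 read in a library. At this depth the median biological coefficient of variation over genes was 20.8%.

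The labels number biological replicates but do not say how many brains or which clutches went into a library. The p-values therefore measure the spread between these samples. No pair of replicates held the same library. The chi-square per gene between replicates of a group, over genes with at least 20 reads in the pair, lay between 6.91 and 52.8, and the Pearson correlation of their log2 CPM across genes lay between 0.8878 and 0.9818.

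Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filterByExpr on the 4 groups, which left 26570 genes, libraries were scaled by TMM, and the quasi-likelihood F test with robust dispersion was run in 1 fit of all 12 libraries. The contrasts were thioridazine against control at each stage, the difference between those contrasts, and NF 47 against NF 45 within controls and within thioridazine. P-values were adjusted by Benjamini and Hochberg over all genes tested, and an adjusted p under 0.05 was called. Fold changes are log2 with the standard error of the fit. CPM values use the TMM-scaled library totals, and log2 CPM values use a prior count of 2. Fixed lists of genes, 34 in number, covered neural cell classes, regional patterning, signalling pathways, stress and metabolism, and markers of cell types that dissected brain tissue could carry. They were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01, again with a correlation estimated for each list, and with fry. Tests, contrasts, lists and most alternatives were choices made before the data were examined.

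In simulated counts with the real means and library sizes, 100 genes changed by a log2 fold of 1 and 100 by 2 were recovered at rates of 25% and 80% for the NF 45 contrast. Rates were 32% and 76% for the NF 47 contrast, 27% and 73% for the stage contrast in controls and 35% and 77% for the stage contrast in thioridazine. These simulations covered 26570 genes. False calls numbered 3 for the NF 45 contrast and 8 for the NF 47 contrast. With the replicate number within stage as a block, described below, the rates were 26% and 77% at NF 45, with 12 false calls. At NF 47 they were 23% and 71% with that block, with 4 false calls. A shift of 0.3 put on 1 list of the NF 45 contrast gave an adjusted p of 2.529e-20 at the preset correlation and 6.92e-05 with an estimated correlation, with 0 of the other lists called. The simulated genes varied independently, without pairs or outlying libraries. This therefore cannot show how often changed genes are found or lists are falsely called in the real counts. There, other splits of the NF 45 libraries called up to 21 lists at the preset correlation.

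The replicate numbers were checked for pairing, because all groups share them. The check took the deviation of each library's log2 CPM from its group mean and correlated it between same-numbered control and thioridazine libraries. These correlations were 0.575, 0.845 and 0.449 at NF 45 and 0.291, 0.318 and 0.54 at NF 47, all above the required 0.1. Between stages they were -0.0556, -0.128 and 0.226 in controls and 0.186, 0.236 and 0.429 in thioridazine. By that threshold the numbers pair control and thioridazine libraries within a stage. At NF 45 it did not single out the numbering of replicates 1 and 3, since control 3 correlated at 0.483 with thioridazine 1 and control 1 at 0.359 with thioridazine 3. Across stages all correlations passed 0.1 in thioridazine but not in controls, so the pairs of both stages were treated as separate although those of thioridazine were related. This comes from the data, since the labels name no shared clutch, plate or day. A fit with the replicate number within each stage as a block was added for this reason, as was the mean of its treatment coefficients over both stages. Differences of list means within the 6 pairs were tested with an exact two-sided sign-flip test over 64 assignments, whose smallest possible p is 0.03125.

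The planned rule named genes from among those called, which left few names because the edgeR fit called none. It kept the drd2 and th copies and the 4 genes of each sign with the smallest interaction p. A rule chosen after the data were seen added up to 3 members with the smallest p from each of the 7 lists with the smallest camera p in the treatment comparisons, and 2 members of 4 lists in the stage comparisons. It also added named genes called in the fits blocked within stage, genes called by DESeq2 at NF 45, and the 4 genes of each sign with the smallest DESeq2 p in the stage comparisons. Symbols that only number a locus or clone were not named.

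Other settings chosen at the outset were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with sample quality weights, no low-count filter, a filter of CPM of at least 1 in at least 3 libraries, a fit of only the groups compared, summed .L and .S copies, a test against a log2 fold of 0.5, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were fits without both NF 45 libraries numbered 2, the block within stage, and DESeq2 with that block.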

Results

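Gene expression was measured in whole brains of Xenopus laevis tadpoles, a frog used widely in developmental biology, at NF 45 and NF 47, before metamorphosis. Embryos had met thioridazine while the neural tube formed, and the brains were collected at tadpole stages from animals with drug-induced brain abnormalities and from untreated controls. Each of the 4 groups had 3 libraries. Read totals per library lay between 12843954, in NF 45 control replicate 3, and 18164871, in NF 45 thioridazine replicate 3. CPM levels are given below as mean ± SD over the 3 libraries of a group, and log2 fold changes with their standard error.

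The 2 libraries that stood farthest from the rest were replicate 2 of both NF 45 groups. On component 1, which held 46.8% of the variance of log2 CPM, they lay at 104.4 for the control and 118.3 for thioridazine, while the other 10 libraries lay between -56.16 and 9.6. Genes of skin and other epithelium, ribosomal proteins and oxidative phosphorylation were low in both of them. Replicate 3 of the NF 45 controls stood apart on component 2 at -67.18. It held most of the reads of liver and gut genes, such as fgb.L, a fibrinogen chain, at 42 CPM against 0.579 and 0.748 CPM in the other NF 45 controls. The treatment groups were not separated by these components at NF 45.

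**Figure D1:**
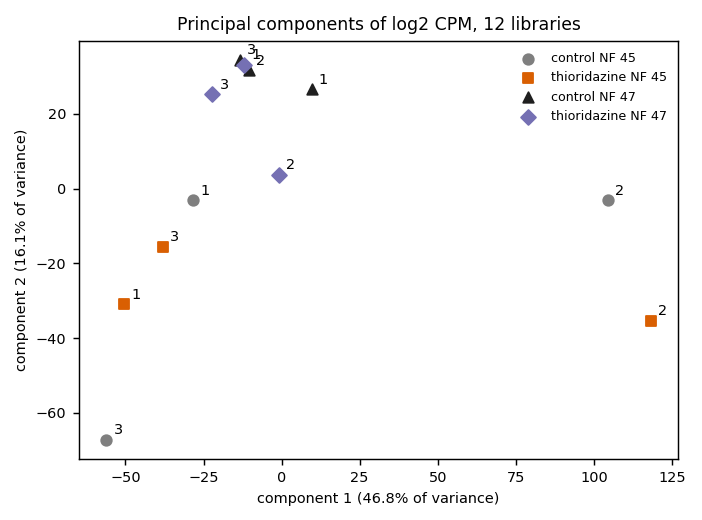
Principal components of log2 CPM over 26570 genes, with component 1 on the x axis (46.8% of the variance) and component 2 on the y axis (16.1%). Each point is 1 library with its replicate number. The NF 45 libraries numbered 2 lie at 104.4 and 118.3 on component 1, and the NF 47 libraries lie between -22.21 and 9.6.

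The first question was how brains of exposed tadpoles differed from control brains at NF 45. Genes of leukocytes, the cell cycle, forebrain patterning and the lysosome were higher in exposed brains as groups at camera's preset correlation, mostly by small amounts per gene. With an estimated correlation none of them was called (adjusted p = 0.0882 for leukocytes, 0.226 for the lysosome and 0.304 for the other two). The list of microglia, macrophages and leukocytes had the largest shift among these, with a median log2 fold change of 0.57 and 34 of 39 members higher. In it, tyrobp.L (gene number 108696884), a signalling adaptor of myeloid cells, stood at 1.8 ± 0.445 CPM in controls and 4.63 ± 1.07 CPM in exposed brains, a log2 fold change of 1.36 ± 0.275. The gene ncf1.L, which encodes a subunit of the phagocyte oxidase, differed by 1.38 ± 0.387.

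The cell cycle and DNA replication list was higher in 57 of 59 members at NF 45, with a median log2 fold change of 0.24. The kinetochore motor cenpe.L differed by 0.39 ± 0.138, the condensin subunit ncapg.L by 0.30 ± 0.105 and the mitotic kinase cdk1.S by 0.33 ± 0.14. Of the 67 forebrain patterning genes 51 were higher, with a median of 0.16. Both copies of lhx8, a homeobox gene of ventral forebrain neurons, differed by about the same amount, 0.67 ± 0.161 for lhx8.L and 0.68 ± 0.178 for lhx8.S. The homeobox gene dlx5.S, active in inhibitory forebrain neurons, differed by 0.56 ± 0.147. Lysosome genes were higher in 39 of 49 members, with a median of 0.18. The protease legumain, lgmn.L (379601), stood at 69.3 ± 10.4 CPM in controls and 106 ± 9.2 CPM in exposed brains, cathepsin ctsl.L differed by 0.78 ± 0.211 and the peptidase tpp1.L by 0.33 ± 0.0935.

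Of 54 neuropeptide and hypothalamus genes, 39 were higher at NF 45, with a median log2 fold change of 0.10. The gene of gonadotropin-releasing hormone II, gnrh2.L (108697134), stood at 10.4 ± 1.5 CPM in controls and 22.4 ± 1.67 CPM in exposed brains, a log2 fold change of 1.11 ± 0.198. The opioid peptide precursor pdyn.S differed by 0.59 ± 0.126 and oxt.S, of the oxytocin family, by 0.96 ± 0.257. Ion channel genes were lower in 77 of 102 members, with a median of -0.10. The glial potassium channel kcnj10.L differed by -0.39 ± 0.169, the calcium channel subunit cacna2d2.S by -0.51 ± 0.272 and the chloride channel clcn2.L by -0.32 ± 0.159. Pituitary genes were lower in 12 of 19 members, with a median of -0.13.

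Camera called 17 of the 34 lists at NF 45, 10 higher and 7 lower, and with an estimated correlation it called 0. Leukocytes had an adjusted p of 4.99e-22 (adjusted p = 0.0882 with an estimated correlation). The cell cycle had an adjusted p of 4.99e-22 (adjusted p = 0.304 with an estimated correlation), forebrain patterning 4.46e-14 (adjusted p = 0.304 with an estimated correlation) and the lysosome 2.43e-10 (adjusted p = 0.226 with an estimated correlation). Leaving out any 1 library kept these 4 calls. Their differences in the NF 45 pairs numbered 1, 2 and 3 were uneven, at 0.509, 0.956 and 0.097 for leukocytes and 0.0797, 0.137 and 0.431 for the cell cycle. Forebrain patterning had 0.0292, 0.182 and 0.352, and the lysosome 0.269, 0.218 and 0.0248. For neuropeptides the adjusted p was 5.49e-09 (adjusted p = 0.304 with an estimated correlation), and 0.0535 without replicate 3 of the controls. For ion channels it was 0.000208 (adjusted p = 0.547 with an estimated correlation), and 0.609, 0.121 and 0.056 without control replicate 2, thioridazine replicate 1 and thioridazine replicate 3. For the pituitary list it was 0.00241 (adjusted p = 0.304 with an estimated correlation), and 0.112, 0.204 and 0.116 without control replicate 1, thioridazine replicate 2 and both libraries numbered 2. No member of any list was called over all genes. Adjusted over the list alone, 2 leukocyte genes, 2 neuropeptide genes, 1 lysosome gene and 1 choroid plexus gene were called, and 0 members of the other 30 lists.

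The liver, pancreas and gut list was called lower at NF 45, with a median log2 fold change of -1.57 and an adjusted p of 0.000592 (adjusted p = 0.504 with an estimated correlation). This rested on replicate 3 of the controls, in which rbp4.L stood at 246 CPM against 2.24 and 1.25 CPM in the other controls. Without that library rbp4.L differed by 0.97 and the list was called higher, with an adjusted p of 0.0178, and without thioridazine replicate 2 the adjusted p was 0.0792. The other 9 called lists had small medians or few members. They were the retina (median 0.09, adjusted p 0.000718), neural progenitors (0.13, 0.00336), oxidative phosphorylation (0.07, 0.00476), the Wnt pathway (-0.09, 0.00858), monoamines (0.06, 0.0108), immediate early genes (-0.10, 0.0114), glutamate, GABA, glycine and acetylcholine signalling (-0.09, 0.0319), ribosomal proteins (0.08, 0.0319) and the lens (-0.59, 0.0452). With an estimated correlation their adjusted p lay between 0.504 and 0.885, and each of the 6 NF 45 libraries ended at least 1 of these 9 calls when left out, with adjusted p up to 0.938. Of these, 3 turned direction past the threshold: ribosomal proteins without control replicate 2 (0.000262) or thioridazine replicate 3 (5.1e-07), oxidative phosphorylation without thioridazine replicate 3 (0.0394) and transmitter signalling without control replicate 2 (0.0245). Such a fit leaves the same-numbered partner of the library unmatched. Within pairs transmitter signalling was lower in all 3 (-0.0738, -0.127 and -0.117), while ribosomal proteins and oxidative phosphorylation differed in sign between pairs. Without both libraries numbered 2, the calls of monoamines (0.144), immediate early genes (0.337), transmitter signalling (0.209) and the retina (0.283) were lost. With the replicate block within stage the lens call was lost, at an adjusted p of 0.189.

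No single gene was called at NF 45 by edgeR among 26570 genes, where 526 had an unadjusted p under 0.05 and chance alone would give 1328. The smallest adjusted p was 0.345. This fit leaves the shared deviations of same-numbered libraries in its spread, and with the replicate block within stage 1521 genes had such an unadjusted p. The 0 calls therefore do not show that no gene differed. DESeq2 called 9 genes, all higher, and limma-voom with quality weights called 0. They included gnrh2.L (adjusted p 0.00162), cltrn.L (0.0248) and lgmn.L (0.0384). With the replicate block within stage, edgeR called 6 genes, 5 higher and 1 lower, and DESeq2 with that block called 22, 16 higher and 6 lower. The smallest adjusted p of the blocked edgeR fit, 0.00229, belonged to c1qtnf9b.L, with 3, 1 and 0 reads in controls and 98, 278 and 44 in exposed brains. Growth hormone, gh1.S (399154), fell in the blocked edgeR fit with a log2 fold change of -1.18 ± 0.153 and an adjusted p of 0.0338, from 21.7 ± 6.18 to 9.97 ± 5.13 CPM. The galectin gene lgals9c.S rose by 1.07 ± 0.143, with an adjusted p of 0.0338, and the other 3 calls had no descriptive symbol. Without both NF 45 libraries numbered 2, the blocked fit called 0 genes, with 1594 at an unadjusted p under 0.05, and DESeq2 was not run on that set.

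Thioridazine blocks dopamine receptors, so the dopamine receptor gene drd2 and the tyrosine hydroxylase gene th, which encodes the rate-limiting enzyme of dopamine synthesis, were followed whatever their result. At NF 45, th.L differed by 0.56 ± 0.201 and th.S by 0.54 ± 0.258, while drd2.L differed by 0.19 ± 0.201 and drd2.S by -0.07 ± 0.207. At NF 47, th.L differed by 0.12 ± 0.198, th.S by 0.03 ± 0.256, drd2.L by 0.10 ± 0.199 and drd2.S by 0.02 ± 0.205. All had an adjusted p of 1 in edgeR. Within the 6 pairs of both stages, drd2.L was higher in the exposed library in 6, th.L and th.S in 5 and drd2.S in 2. With the replicate block within stage none was called, and th.L at NF 45 had an adjusted p of 0.682. In fits without the block, where a left-out library leaves its partner unmatched, signs could turn. The sign of drd2.L at NF 45 turned without thioridazine replicate 2 (-0.05), and that of drd2.S turned without control replicate 2 (0.11) and without thioridazine replicate 1 (0.03). Both drd2 copies summed differed by 0.07 at NF 45. At NF 47 the sign of th.S turned without control replicates 2 and 3 and thioridazine replicate 2 (-0.02, -0.05 and -0.24) and with limma-voom (-0.13). The sign of drd2.S turned without control replicate 3 and thioridazine replicate 1 (-0.02 and -0.11).

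The same question was asked at NF 47, where the cell cycle list was again higher in exposed brains and genes of synaptic transmission were lower at the preset correlation. With an estimated correlation none of these lists was called (adjusted p = 0.683 for each). Of 59 cell cycle genes 56 were higher, with a median log2 fold change of 0.15. The mitotic kinesin kif20a.L differed by 0.33 ± 0.132, the condensin subunit smc4.L by 0.32 ± 0.129 and topoisomerase top2a.L by 0.29 ± 0.139. Of 46 synapse and synaptic vesicle genes 38 were lower, with a median of -0.12, among them the vesicle protein gene vamp2.S (394286), at 208 ± 12.7 CPM in controls and 170 ± 1.47 CPM in exposed brains. The complexin gene cplx2.S differed by -0.36 ± 0.21 and the vesicle gene syngr1.S by -0.30 ± 0.165. Of 55 genes of glutamate, GABA, glycine and acetylcholine signalling 40 were lower, with a median of -0.13. The nicotinic receptor genes chrna4.L (108702037) and chrna7.L differed by -0.50 ± 0.147 and -0.33 ± 0.167, and the GABA receptor gene gabra5.L by -0.47 ± 0.196. Of 102 ion channel genes 65 were lower, with a median of -0.10, including the sodium channel subunit scn4b.L at -0.39 ± 0.156 and the potassium channel kcnn1.S at -0.36 ± 0.19.

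Of the lists of tissues outside the brain, muscle, retina and cartilage were higher in exposed libraries at NF 47 at the preset correlation (adjusted p = 0.683, 0.683 and 0.92 with an estimated correlation). Others were not called, such as skin, with 0.363, -0.0553 and 0.000647 in the 3 pairs, and red blood cells and the lens, with mean paired differences of -0.0538 and -0.0607. Skin was called with the replicate block within stage. Liver, pancreas and gut was not called either, although it was higher in all 3 pairs (0.247, 0.216 and 0.314). Skeletal and cardiac muscle genes were higher in 46 of 61 members, with a median log2 fold change of 0.57, although from low levels, as in ckm.S at 1.09 ± 0.444 CPM in controls and 1.91 ± 0.917 CPM in exposed brains. The myosin gene myh4.L differed by 0.83 ± 0.536 and neb.L, the nebulin gene of muscle filaments, by 0.64 ± 0.481. The muscle list was higher in the same NF 47 pairs (0.284, 0.491 and 0.547) in which the synapse list was lower (-0.115, -0.159 and -0.13). Whether a different share of outside tissue lowered the lists of synaptic transmission was not tested. Retina and pigment epithelium genes were higher in 44 of 53 members, with a median of 0.41, led by the melanin pathway genes dct.L at 1.32 ± 0.432, mlana.L at 1.08 ± 0.428 and pmel.S at 1.01 ± 0.533. Cartilage, bone and connective tissue genes were higher in 50 of 62 members, with a median of 0.19, and the examples col3a1.L, mmp13.S and col5a2.L differed by 0.54 ± 0.381, 0.93 ± 0.564 and 0.25 ± 0.131.

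Camera called 14 of the 34 lists at NF 47, 9 higher and 5 lower, and with an estimated correlation it called 0. The adjusted p was 6.73e-13 for the cell cycle, 1.91e-08 for muscle, 7.78e-06 for the synapse, 5.21e-05 for transmitter signalling and 0.001 for ion channels, each with an adjusted p = 0.683 with an estimated correlation. These 5 calls were kept when any 1 library was left out. The retina list had an adjusted p of 7.78e-06 (adjusted p = 0.683 with an estimated correlation), and 0.829 without thioridazine replicate 3. The cartilage list had 0.000326 (adjusted p = 0.92 with an estimated correlation), and 0.124 without control replicate 1. The other 7 called lists were neural progenitors (median 0.09, adjusted p 0.00196), forebrain patterning (0.08, 0.00196), leukocytes (0.13, 0.00284), the Notch pathway (0.10, 0.00381), oxidative phosphorylation (-0.05, 0.00952), the lysosome (0.08, 0.00952) and myelin (-0.03, 0.0278). Their adjusted p was 0.683 with an estimated correlation, except 0.925 for oxidative phosphorylation, and each of the 6 NF 47 libraries ended at least 1 of these 7 calls when left out. With the replicate block within stage the myelin call was lost, at an adjusted p of 0.114, as it was without both NF 45 libraries numbered 2 (0.0735). No list member was called over all genes, and adjusted over the list alone only 1 pituitary gene was.

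No single gene was called at NF 47 by edgeR, where 291 had an unadjusted p under 0.05 (1157 with the replicate block within stage), nor by DESeq2 or limma-voom. With the replicate block within stage edgeR called 1 gene, gpnmb.L (733250), a glycoprotein gene of pigment cells and macrophages, which rose by 1.31 ± 0.134 with an adjusted p of 0.0124. Its level was 8.25 ± 2.96 CPM in controls and 20.5 ± 7.49 CPM in exposed brains. DESeq2 with that block called 50 genes, 45 higher and 5 lower.

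**Figure D2:**
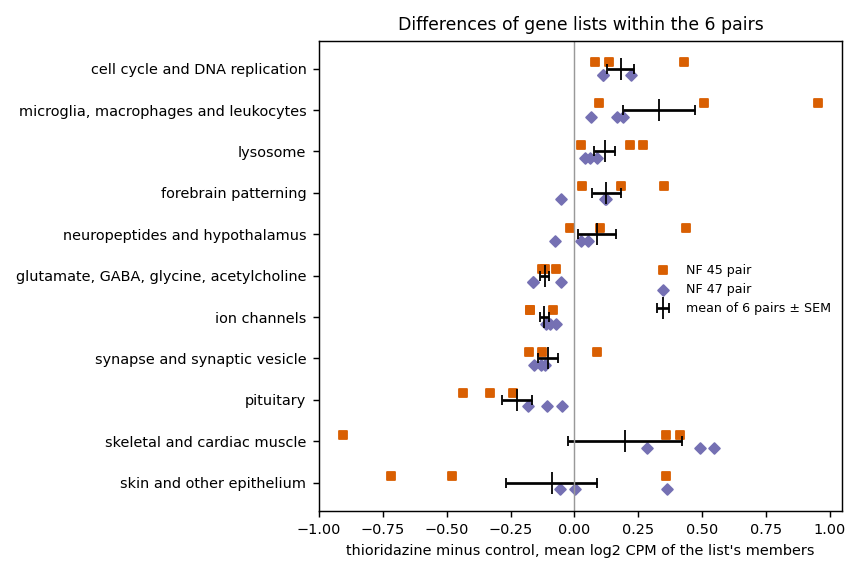
Difference between the thioridazine and the control library of the same replicate number, as the mean log2 CPM of a list's members (x axis), for 11 lists (y axis). Squares are the 3 pairs at NF 45, diamonds the 3 pairs at NF 47, and the bars the mean of the 6 pairs ± SEM. Cell cycle, leukocyte and lysosome lists lie above 0 in 6 of 6 pairs, and transmitter signalling, ion channel and pituitary lists lie below 0 in 6 of 6 pairs.

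Since same-numbered libraries of a stage deviated together, the treatment difference was also averaged over both stages within the 6 pairs, a comparison added after the data were seen. At NF 45 the numbering of replicates 1 and 3 was not singled out by these deviations. It called 25 of 26570 genes, 22 higher and 3 lower, and 7 of them had no descriptive symbol. The 3 that fell were all growth hormone genes, gh1.S with a log2 fold change of -0.92 ± 0.105 (adjusted p 0.00744), gh1.L with -0.79 ± 0.111 (adjusted p 0.0212) and gh2.S with -0.84 ± 0.12 (adjusted p 0.0212), each lower in 6 of 6 pairs. Among the genes that rose, some are known from pigment cells, a grouping made after the calls were seen and not tested: gpnmb.L by 1.1 ± 0.0926 (adjusted p 0.00114), dct.L by 1.30 ± 0.179, mlana.L by 1.25 ± 0.187, slc24a5.L by 1.00 ± 0.135, tspan36.L by 0.96 ± 0.137 and ednrb2.S by 0.70 ± 0.11. Other pigment cell genes were not called, such as pmel.S at 0.89 (adjusted p 0.158), pmel.L at 0.64 (0.406) and tyrp1.L at 0.61 (0.471). The peroxidase gene epx.L, known from granulocytes, rose by 0.90 ± 0.114, the matrix protease gene mmp7.L by 0.85 ± 0.0978, lgals9c.S by 0.74 ± 0.101, lgmn.L by 0.47 ± 0.0725, the collagen gene col3a1.S by 0.64 ± 0.0892, igfbp2.S by 1.11 ± 0.173 and gnrh2.L by 0.81 ± 0.124. All adjusted p of these lay between 0.00114 and 0.0428, in edgeR.

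The number of calls in this average depended on single pairs. It was 1 without the NF 47 pair numbered 3, 8 without the NF 47 pair numbered 2, 12 without the NF 47 pair numbered 1, 15 without the NF 45 pair numbered 2 and 303 without the NF 45 pair numbered 3. The call of gpnmb.L was kept in all 6 of these fits, and that of gh1.S in all but the one without the NF 47 pair numbered 3 (adjusted p 0.0584). Each of the other genes named here lost its call without at least 1 NF 47 pair, where the adjusted p of dct.L reached 0.258, that of lgmn.L and gnrh2.L 0.333 and that of gh2.S 0.223.

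**Figure D3:**
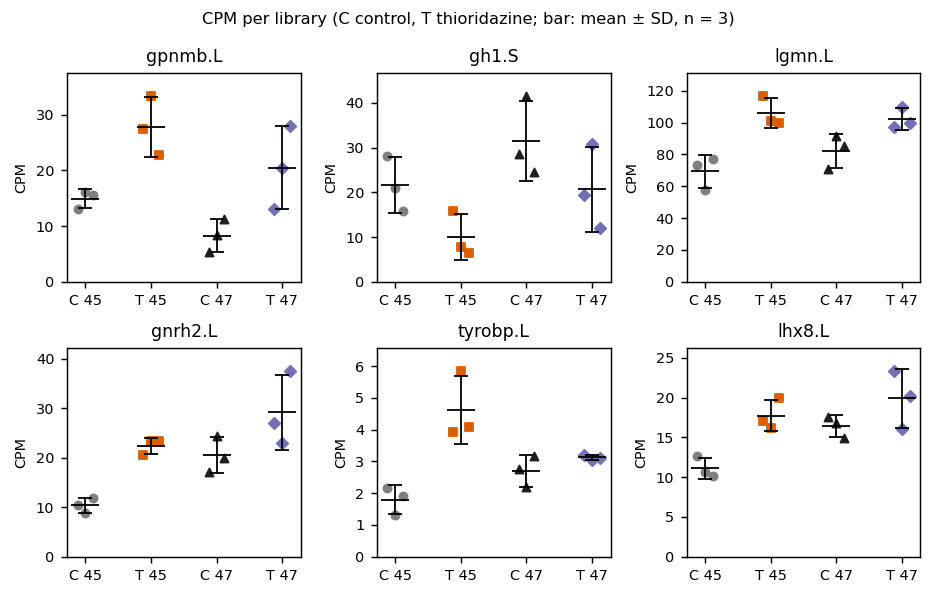
CPM per library of 6 genes (y axes) in controls (C) and thioridazine (T) at NF 45 and NF 47 (x axes), with the mean ± SD of 3 libraries. The genes gpnmb.L and lgmn.L are higher and gh1.S is lower in the exposed library of each of the 6 pairs.

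Among lists, 13 were called in the average at the preset correlation, 9 higher and 4 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.18. The cell cycle list had a median of 0.19 and an adjusted p of 3.15e-22 (adjusted p = 0.34 with an estimated correlation), and the pituitary list a median of -0.13 and an adjusted p of 1.26e-05 (adjusted p = 0.18 with an estimated correlation). Over all genes, 3 pituitary, 2 retina, 1 lysosome, 1 neuropeptide, 1 cartilage and 1 choroid plexus list members were called. Adjusted over the list alone, 19 forebrain patterning, 11 lysosome, 8 pituitary, 7 cartilage and 5 leukocyte genes were called. In the mean of the 6 pairs, lists lay on 1 side in 6 of 6 pairs for the cell cycle (0.18 ± 0.0536, SEM), leukocytes (0.33 ± 0.141), the lysosome (0.12 ± 0.0413), ion channels (-0.12 ± 0.0182), transmitter signalling (-0.12 ± 0.0182) and the pituitary (-0.22 ± 0.0583). For each of these the exact two-sided sign-flip p was 0.03125, the smallest 6 pairs can give, and it was 0.177 after Benjamini-Hochberg adjustment over the 34 lists.

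Whether the treatment difference changed between stages was tested by the interaction. No gene was called by edgeR, where 91 had an unadjusted p under 0.05 (402 with the replicate block within stage), nor by DESeq2, limma-voom or the fits with a block. The genes with the smallest p and a higher difference at NF 47 were vipr2.S and tuba1al.L, both under 2 CPM in every library, rpgrip1l.L, which encodes a ciliary protein, at 0.51 ± 0.172, and the prolactin gene prl.2.S at 0.99 ± 0.345. The last stood at 14 ± 2.04 and 16.8 ± 4.39 CPM in control and exposed brains at NF 45 and at 15.1 ± 2.86 and 35.8 ± 10.4 CPM at NF 47. Those with a lower difference at NF 47 were dmrta2.S, a gene of the dorsal forebrain, at -0.83 ± 0.22, avp.S, of the vasopressin family, at -0.85 ± 0.258, pdyn.S at -0.57 ± 0.176 and clrn1.L at -1.51 ± 0.469. All 8 had an adjusted p of 1 in edgeR.

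As groups, leukocyte genes had a smaller treatment difference at NF 47 than at NF 45, with a median interaction of -0.33 over 39 members (adjusted p 1.37e-09, and adjusted p = 0.585 with an estimated correlation). Neuropeptide genes also had a smaller one, at -0.16 over 54 members (adjusted p 1.34e-08, and adjusted p = 0.585 with an estimated correlation), while muscle genes had a larger one at NF 47, at 0.39 over 61 members (adjusted p 5.72e-08, and adjusted p = 0.585 with an estimated correlation). Camera called 18 lists, 9 in each direction, and 0 with an estimated correlation. Without both NF 45 libraries numbered 2 the leukocyte interaction had an adjusted p of 0.0516. The third NF 45 pair stood apart in the other 2 lists, where muscle differed by 0.413, 0.357 and -0.907 at NF 45 and 0.284, 0.491 and 0.547 at NF 47, and neuropeptides by -0.0185, 0.0993 and 0.439 and by 0.0515, -0.0761 and 0.0272. No member was called in any of the 34 lists, over all genes or adjusted over the list alone.

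Treatment differences at NF 45 and NF 47 were correlated across genes, with a Pearson r of 0.309 and a Spearman correlation of 0.301 over 26570 genes, of which 62.3% had the same sign at both stages. Genes are not independent replicates, so the paired differences were also recomputed for all 32 ways to exchange the labels within pairs. Their correlation was 0.355 with the real labels, higher than in any other exchange, where the highest was 0.225. The one-sided exact p was 0.03125, the smallest that 32 exchanges can give. It counts only correlations as high as the real one. Another exchange gave -0.355, the same size with the opposite sign, and a two-sided count would include it. The test also rests on a pairing that was found from the data and is not named in the labels. These exchanges treat the pairs of both stages as independent, although same-numbered thioridazine libraries also deviated together across stages (0.186, 0.236 and 0.429). Leaving out 1 library gave an r between 0.15, without control NF 45 replicate 2, and 0.486, without control NF 45 replicate 3.

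The final comparisons asked how the brain changed from NF 45 to NF 47 within each treatment group. In controls, neuropeptide genes rose, with 53 of 54 members higher and a median log2 fold change of 0.59, and this list passed camera with an estimated correlation as well (adjusted p 2.41e-41, and adjusted p = 0.0171 with an estimated correlation). Adjusted over the list alone, 37 of its members were called. The granule protein gene chga.S went from 116 ± 5.23 to 170 ± 6.72 CPM and the enkephalin precursor penk.L (495184) from 55 ± 7.54 to 94.7 ± 6.42 CPM. Synapse genes were higher in 38 of 46 members, with a median of 0.23 (adjusted p 1.37e-10, and adjusted p = 0.452 with an estimated correlation), and 14 were called adjusted over the list alone. The synuclein gene snca.L stood at 87.1 ± 4.98 CPM at NF 45 and 149 ± 7.82 CPM at NF 47, and snap25.L, of the vesicle fusion complex, at 396 ± 47.5 and 564 ± 16.7 CPM.

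Cell cycle genes were lower at NF 47 in 58 of 59 members in controls, with a median of -0.25 (adjusted p 6.08e-12, and adjusted p = 0.454 with an estimated correlation), including cdc6.L, which loads replication origins, at -0.48 ± 0.115 and the checkpoint kinase bub1.L at -0.39 ± 0.109. Ribosomal protein genes were higher in 123 of 126 members, with a median of 0.25 (adjusted p 4.32e-09, and adjusted p = 0.561 with an estimated correlation), although their call was lost without control NF 45 replicate 2 (adjusted p 0.153), in which rpl31.S stood at 287 CPM against 426 and 425 CPM in the other 2. Muscle genes were lower, with a median of -1.01 (adjusted p 2.73e-07, and adjusted p = 0.522 with an estimated correlation). In all, camera called 24 lists in controls, 15 higher and 9 lower, and only neuropeptides with an estimated correlation. Myelin and oligodendrocyte genes were among them, with a median of 0.22 (adjusted p 4e-05, and adjusted p = 0.265 with an estimated correlation). No list member was called over all genes, and adjusted over the list alone 2 myelin genes and 0 cell cycle, ribosomal and muscle genes were.

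No single gene was called between the stages in controls by edgeR, where 2965 had an unadjusted p under 0.05 against 1328 by chance and the smallest adjusted p was 0.116. DESeq2 called 422 genes, 337 higher and 85 lower, limma-voom with quality weights called 911, 634 higher and 277 lower, and edgeR without both NF 45 libraries numbered 2 called 817, 464 higher and 353 lower. The genes with the smallest DESeq2 p were fxyd6.S, an ion pump regulator, at 0.62 ± 0.0926, faim2.L, an inhibitor of apoptosis in neurons, at 1.05 ± 0.133, snca.L at 0.78 ± 0.112 and tmeff2.L at 0.75 ± 0.106 among those higher, with DESeq2 adjusted p between 2.52e-10 and 1.21e-06. Among those lower they were pprc1.L at -0.76 ± 0.134, tuba5.S, an alpha-tubulin gene, at -0.51 ± 0.11, tacc3.L, of the mitotic spindle, at -0.54 ± 0.106 and klf11.S at -0.60 ± 0.122, with DESeq2 adjusted p between 0.000296 and 0.00187. The folds and errors are those of edgeR.

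In thioridazine brains, neuropeptide genes were higher at NF 47 in 52 of 54 members, with a median of 0.38 (adjusted p 1.2e-22, and adjusted p = 0.11 with an estimated correlation), and 14 were called adjusted over the list alone. The peptide gene cartpt.L went from 7.64 ± 1.28 to 15 ± 1.78 CPM. Cell cycle genes were lower in 58 of 59 members, with a median of -0.32 (adjusted p 3.53e-21, and adjusted p = 0.339 with an estimated correlation), and 13 were called adjusted over the list alone. The cyclin gene ccne2.S went from 19.4 ± 3.22 to 10.7 ± 2.31 CPM. Immediate early genes were higher in 33 of 45 members, with a median of 0.27 (adjusted p 1.11e-09, and adjusted p = 0.11 with an estimated correlation), and 8 were called adjusted over the list alone, with jun.S (379050) at 22.7 ± 1.52 and 45.1 ± 5.91 CPM and junb.L at 17.4 ± 0.865 and 27.5 ± 0.118 CPM. Pituitary genes were higher in 14 of 19 members, with a median of 0.81 (adjusted p 5.73e-06, and adjusted p = 0.146 with an estimated correlation), and 7 were called adjusted over the list alone. These 4 calls were kept when any 1 library was left out. Ribosomal protein genes were higher in 122 of 126 members, with a median of 0.16 (adjusted p 3.55e-06, and adjusted p = 0.95 with an estimated correlation), and the call was lost without thioridazine NF 45 replicate 2 (adjusted p 0.305) or thioridazine NF 47 replicate 3 (0.178), and without both NF 45 libraries numbered 2 (0.356). Synapse genes had a median of 0.20 (adjusted p 3.55e-06, and adjusted p = 0.864 with an estimated correlation).

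By edgeR 0 genes were called between the stages in thioridazine, with 2560 at an unadjusted p under 0.05 and a smallest adjusted p of 0.102. DESeq2 called 263 genes, 146 higher and 117 lower, limma-voom called 1, and edgeR without both NF 45 libraries numbered 2 called 3. The smallest DESeq2 p among genes that were higher belonged to jarid2.L, a partner of the Polycomb complex, which went from 251 ± 33.6 to 647 ± 79 CPM (DESeq2 adjusted p 3.07e-11), followed by fxyd6.S, tmeff2.L and jun.S. Among those lower it belonged to ddx3x.L, an RNA helicase gene, at -0.58 ± 0.107, smox.L, of polyamine breakdown, at -0.70 ± 0.111, tuba5.S at -0.60 ± 0.11 and dlgap5.S, of the mitotic spindle, at -0.60 ± 0.0996, with DESeq2 adjusted p between 1.4e-05 and 0.000108. Camera called 12 lists, 9 higher and 3 lower, and 0 with an estimated correlation. No list member was called over all genes, and adjusted over the list alone 1 synapse gene and 0 ribosomal genes were.

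**Figure D4:**
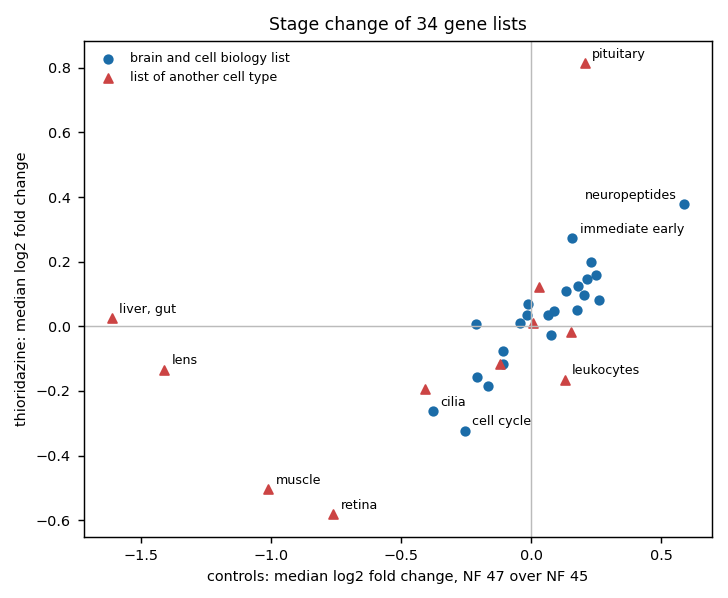
Median log2 fold change from NF 45 to NF 47 of the 34 lists, in controls (x axis) and in thioridazine (y axis). Circles are lists of brain and cell biology and triangles lists of other cell types. Neuropeptides lie at 0.59 and 0.38 and the cell cycle at -0.25 and -0.32.

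Stage changes in controls and in thioridazine were then set side by side. Of the genes DESeq2 tested in both, 315 were called higher in controls and 146 in thioridazine, with 90 shared, and 73 and 117 were called lower, with 33 shared. Shared genes include fxyd6.S and tmeff2.L among those higher and tuba5.S among those lower. Across 26570 genes the log2 fold changes had a Pearson r of 0.659 and a Spearman correlation of 0.69. The libraries of both groups are paired by number within a stage, which alone makes their stage changes covary, so neither the shared calls nor the correlation has a valid chance value. On mean log2 CPM the covariance was 0.099, and same-numbered libraries accounted for an estimated 0.109, which leaves -0.0098, a value with no spread. Without both NF 45 libraries numbered 2, a choice made after the data were seen, the covariance was 0.14, with 0.0194 from same-numbered libraries and 0.121 left, so what remains beyond the pairing depends on those 2 libraries.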

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

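Of the tests in this part, those of tissue from outside the brain, as less of it for the cell cycle list and more of it for the leukocyte list, were chosen only after the result was seen, as were the fits without single pairs and without both NF 45 libraries numbered 2. Each of 18 lists is given here because its treatment difference was not the same at NF 45 and NF 47 by the interaction test at the preset correlation. None of them passed with an estimated correlation, where the smallest adjusted p was 0.585.

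Leukocyte genes had a smaller treatment difference at NF 47 than at NF 45, by a median of -0.33 (adjusted p 1.37e-09), neuropeptide genes a smaller one by -0.16 (1.34e-08) and muscle genes a larger one by 0.39 (5.72e-08). These 3 held when any 1 of the 12 libraries was left out, and the leukocyte call was lost without both NF 45 libraries numbered 2 (0.0516). The NF 45 pair numbered 3 stood apart for muscle (-0.907 against 0.413 and 0.357) and for neuropeptides (0.439 against -0.0185 and 0.0993), and these interactions were not refitted without that pair. The interaction of liver, pancreas and gut genes, at 1.32 (9.67e-07), rested on replicate 3 of the NF 45 controls (adjusted p 0.27 without it).

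Among lists with a lower difference at NF 47, oxidative phosphorylation had a median of -0.14 (adjusted p 4.62e-07), forebrain patterning -0.07 (4.77e-05), the lysosome -0.10 (0.000817), monoamines -0.09 (0.00137), the synapse -0.08 (0.00955), the cell cycle -0.07 (0.018) and red blood cells -0.10 (0.0193). Among lists with a higher one, midbrain, hindbrain and spinal patterning had 0.10 (0.00937), the pituitary 0.19 (0.0153), immediate early genes 0.11 (0.018), the Wnt pathway 0.06 (0.0267), skin 0.14 (0.0267), cartilage, bone and connective tissue 0.04 (0.0339) and the Sonic hedgehog pathway 0.11 (0.0363). With the replicate block within stage the Sonic hedgehog and Wnt calls were lost (adjusted p 0.069 and 0.0601). Skin turned direction past the threshold without control NF 45 replicate 3 (0.0441) or thioridazine NF 45 replicate 2 (5.26e-05), and cartilage without thioridazine NF 45 replicate 2 (0.00316). Each of these 14 lists lost its call without at least 1 library, such as oxidative phosphorylation without control NF 45 replicate 2 (0.582), the cell cycle without control NF 47 replicate 3 (0.827) and the synapse without thioridazine NF 45 replicate 2 (0.829).

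Leukocyte genes at NF 45, 39 in number with a median level of 3.79 CPM, were higher in exposed libraries by 0.509, 0.956 and 0.097 in the 3 pairs. More tissue from outside the brain stays open: the skin list (0.358, -0.719 and -0.48) met the bound written against it in 2 pairs, but that bound was too wide, as muscle (0.413, 0.357 and -0.907) and cartilage (0.153, 0.111 and -0.112) were higher in the same first pairs as leukocytes. Blood left in the tissue stays open, because the leukocyte difference exceeded that of 9 globin genes in the first pairs, by 0.939 and 0.438, but fell short of it in the last, by -0.522. Microglia are resident in the brain, so more of these cells could also account for the pattern, which was not tested.

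The cell cycle list was higher in the exposed library of each of the 6 pairs. Less tissue from outside the brain would raise all neural lists alike. The synapse list had a mean paired difference of -0.103 ± 0.0394 (SEM) and was lower in 5 of the 6 pairs, which argues against it in those 5. In the NF 45 pair numbered 3 it stays open. There the cell cycle (0.431) and synapse (0.0889) lists were both higher, while muscle (-0.907) and skin (-0.48) were lower. A lag of exposed brains behind controls in stage would make treatment differences run against the control stage change. The neuropeptide list, which rose with stage in controls, differed by -0.0185, 0.0993 and 0.439 in the NF 45 pairs, of mixed sign. The covariance across genes was 0.0232 at NF 45 and -0.0299 at NF 47, of which 0.0396 and -0.0199 were put down to shared libraries. Corrected for these, it was -0.0163 and -0.01, so its sign at NF 45 rests on the correction. The 95% intervals, from resampled genes and without the spread between libraries, were -0.0204 to -0.0122 and -0.0133 to -0.00733. They met the bound written for a lag. A requirement that the sign hold without any 1 pair was added to that bound, and it was not met (0.0312 at NF 45 without the NF 45 pair numbered 3, and 0.0135 at NF 47 without the NF 47 pair numbered 2), so a lag and a change in proliferation cannot be told apart from these libraries.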

How the results depend on the processing

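The fits without both NF 45 libraries numbered 2, the block within stage, DESeq2 with that block and the average over stages were tests chosen only after the result was seen. Across alternatives, 855 of 1360 values of called lists kept direction and side of the threshold, 472 no longer passed it, 24 moved and 9 reversed. Of 1925 values of named genes, 1768 stayed the same, 72 newly passed, 74 no longer passed and 11 moved. The main edgeR fit called none of these genes in the 5 planned comparisons, so there the same means still uncalled. All 74 losses were among genes called in the average over stages, the only ones with a call to lose. The edgeR count of genes stayed at 0 in all 5 planned comparisons when any 1 library was left out. The cause of the changes below was not tested except where a left-out library itself shows it. Simulated changes of a log2 fold of 1, in counts without pairs or outlying libraries, were recovered at a rate of 25% for the NF 45 contrast, and of 2 at 80%. Rates in the real counts, which have both, were not measured and can be lower.

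Genes called at NF 45 numbered 0, against 9 by DESeq2, 6 with the replicate block within stage and 22 by DESeq2 with that block. At NF 47 they numbered 0, against 1 with the block within stage, 3 with it and without both NF 45 libraries numbered 2, and 50 by DESeq2 with it. For stage in controls the count was 0, against 422 by DESeq2, 911 by limma-voom, 2 with the replicate block across stages and 817 without both NF 45 libraries numbered 2. For stage in thioridazine it was 0, against 263, 1, 1 and 3 in that order. The planned replicate block across stages gave 0 at NF 45, 0 at NF 47 and 0 for the interaction. The average over stages called 25 genes, 15 without both NF 45 libraries numbered 2, and 1 to 303 when 1 pair was left out.

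Lists called with an estimated correlation numbered 0 at NF 45, 0 at NF 47, 0 for the interaction, 1 for stage in controls and 0 for stage in thioridazine, and 0, 0, 0 with the block within stage and 0 for the average. By direction, fry called 0, 0, 0, 1 and 1 lists, and in its mixed form 3, 0, 0, 2 and 4. Leaving out 1 library gave 14 to 22 lists at NF 45, 10 to 18 at NF 47, 12 to 21 for the interaction, and 17 to 26 and 12 to 17 for stage in controls and thioridazine. Leaving out 1 pair gave 12 to 19 for the average. With the block within stage, lists that gained a call were heat shock (adjusted p 0.0465), cartilage (0.000493) and skin (7.19e-05) at NF 45, skin (0.00648) at NF 47, and heat shock (0.0334) and ribosomal proteins (0.00402) for the interaction. The lens at NF 45 lost its call (0.189). Beyond these, the myelin, Wnt and Sonic hedgehog lists and the gene calls counted above, the block within stage changed no other call. Without both NF 45 libraries numbered 2, further calls were lost for the interaction in cartilage (0.0848), monoamines (0.0516), immediate early genes (0.418), leukocytes (0.0516), midbrain and hindbrain (0.496), the pituitary (0.114), red blood cells (0.63) and Sonic hedgehog (0.0765). For stage in controls that fit lost the lysosome (0.342), leukocytes (0.687), midbrain and hindbrain (0.607), the pituitary (0.144), red blood cells (0.218), Sonic hedgehog (0.177) and Wnt (0.266). Only its losses are named here, although it also gained calls. It called 16 lists at NF 45 and 15 at NF 47, against 17 and 14 with all libraries.

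Reversed calls all had small medians or rested on 1 library. At NF 45 they were transmitter signalling without control replicate 2 (adjusted p 0.0245, range 9.62e-06 to 0.889), oxidative phosphorylation without thioridazine replicate 3 (0.0394, range 1.96e-10 to 0.249), ribosomal proteins without control replicate 2 (0.000262) and thioridazine replicate 3 (5.1e-07, range 1.06e-16 to 0.801), and liver, pancreas and gut without control replicate 3 (0.0178, range 2.01e-08 to 0.0792). For the interaction they were cartilage without thioridazine NF 45 replicate 2 (0.00316, range 4.88e-11 to 0.667) and skin without control NF 45 replicate 3 (0.0441) and thioridazine NF 45 replicate 2 (5.26e-05, range 1.99e-13 to 0.852). For stage in thioridazine, cartilage reversed without both NF 45 libraries numbered 2 (0.00589). All but the last of these fits left a same-numbered partner unmatched, and transmitter signalling was lower in all 3 NF 45 pairs. The correlation of treatment differences between stages was 0.309, against 0.179 without both NF 45 libraries numbered 2, 0.393 by DESeq2 with the block, and 0.15 to 0.486 without 1 library. Genes called at both stages numbered 0, against 3 by DESeq2 with the block.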

Other observations

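Of the tests in this part, those by DESeq2 on other splits, those of the average over stages and the exchanges within pairs for the interaction were chosen only after the result was seen. Within the retina and pigment epithelium list, the 5 melanin pathway members, picked after their values were seen and so not tested, had a mean log2 difference of 0.93 ± 0.189 (SEM) over the 6 pairs. The 37 members without pigment epithelium genes had a mean of 0.16 ± 0.699, ranging from 2.29 to -2.84. In raw reads, gpnmb.L had 1012 over the 6 control libraries and 2241 over the 6 exposed ones, and dct.L 426 and 1124.

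Within the pituitary list, the 3 growth hormone members, picked because they were called, had a mean paired difference of -0.85 ± 0.156 (SEM), and the 16 other members had -0.11 ± 0.0464. Prolactin, prl.2.S, was higher in 5 of 6 pairs, at 0.73 ± 0.123 in the average (adjusted p 0.0736). The precursor of corticotropin and melanotropin stood at -0.21 (0.48) for pomc.L and at -0.05 (0.888) for pomc.S. Of the copies of the thyrotropin subunit, tshb.S stood at -0.68 (0.399) and was lower in 6 of 6 pairs, and tshb.L stood at -0.13 (0.917) and was lower in 3. The shared glycoprotein hormone subunit stood at -0.54 (0.188) for cga.S, lower in 6 of 6 pairs, and at -0.52 (0.366) for cga.L, lower in 5.

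A few genes were nearly silent in controls and present in most exposed libraries. The C1q-related gene c1qtnf9b.L had 3, 1 and 0 reads in the NF 45 controls and 98, 278 and 44 in the exposed libraries, and 0, 0 and 2 against 0, 11 and 45 at NF 47. The alcohol dehydrogenase gene adh7.S had 1, 2 and 7 against 35, 170 and 63 reads at NF 45, and 0, 0 and 0 against 0, 46 and 16 at NF 47. The gene cltrn.L, which encodes a membrane protein of kidney and pancreas, had 7, 7 and 12 against 29, 231 and 76 reads at NF 45, and 10, 4 and 4 against 10, 54 and 24 at NF 47. In the average c1qtnf9b.L had an adjusted p of 0.00114 and adh7.S of 0.0207, and cltrn.L of 0.191.

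Replicate 2 of both NF 45 groups stood apart from the other 10 libraries on component 1 by a gap 1.44 times the range of those 10. On 1009 genes of the brain lists alone the gap was still 1.24 times the range, on a component with 35.5% of the variance. This met the bound written against tissue from outside the brain, but the test cannot decide it. These lists include genes that other tissues express, such as those of the cell cycle, the lysosome and heat shock. A different share of outside tissue could also shift brain genes together. Ribosomal protein and oxidative phosphorylation genes lay below the other 10 libraries in both, in 2 of the 2 housekeeping lists, so a shared library batch or clutch is consistent with this test. The labels name no batch, and no biological explanation was tested.

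Splits of 6 libraries into 3 and 3 number only 10, too few for a share under 0.05. At NF 45 edgeR called 0 genes with the real split (10 of 10 splits gave as many) and up to 297 in others, lists numbered 17 with up to 21 in others (6 of 10 gave as many), and DESeq2 called 9 with up to 2851 in others (6 of 10). The 4 splits that put both libraries numbered 2 in 1 group called 2851, 858, 499 and 47 genes by DESeq2, which points to sample structure. Among the 4 splits that part all 3 pairs, as the real one does, lists numbered 17, 21, 15 and 20 and DESeq2 calls 9, 20, 0 and 4, the real split first. At NF 47 the real split called 0 genes and no other called more (0, 10 of 10), 14 lists with up to 19 (4 of 10), and 0 genes by DESeq2 with up to 2 (10 of 10).

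For stage in controls, edgeR called 0 genes in all splits (10 of 10), lists numbered 24 with at most 22 in any other (1 of 10) and DESeq2 called 422 with at most 9 in any other (1 of 10). For stage in thioridazine they were 0 in all (10 of 10), 12 lists with up to 22 (8 of 10), and 263 DESeq2 calls with up to 660 (2 of 10). For the interaction, 100 of the 200 possible splits were run, the real one included, and 100 of 100 called at least the 0 genes of the real one, with up to 1439, and 33 of 100 at least its 18 lists, with up to 22. These splits also put whole pairs into 1 group, so the highest counts can reflect the pairs. Among 32 exchanges within pairs, none called a gene for the interaction, and 8 called at least the 18 lists, with up to 21. In the average over stages, 2 of 32 exchanges of labels within pairs called at least the 25 genes, the real one included, and 27 of 32 at least the 13 lists, with up to 22. The other exchange, with 87 genes, turned only the NF 45 pair numbered 3, and the next highest called 8. By these shares a grouping by chance could give both counts.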
